A study of Mus musculus with 6 samples.

How the data were processed

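RNA was measured in 6 libraries of thymic dendritic cells sorted on a BD FACSAria III, 2 each from YG+ pDCs, PBS pDCs and PBS Sirpa+ DCs. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the Ovation SoLo RNA-Seq Mouse kit from 5 ng of total RNA. Tumours had grown for 12 days when microspheres were injected, per the series design. The labels give 1 batch for every sample. Each deposited file held whole-number read counts per gene symbol, not normalised, for 1 sample. The submitters' processing notes name bcl2fastq 2.17 and the mm10 build. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here.

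Each file ended with 5 summary lines that name no gene (no feature, ambiguous, low quality, not aligned and not unique). These lines held 97.7% to 99.5% of all records and stayed out of library sizes and tests. Between 19058505 and 22777061 records per library lay in no gene, and ambiguous records were 0.525% to 0.680% of gene and ambiguous records together. The gene total ran from 177844 to 713966, with 11238 to 13446 genes detected. A gene with no count could have reached 4.20 to 16.9 CPM (counts scaled to library size) in a library, at 3 counts of the gene total. Shares of reads carry 95% Wilson intervals. Of 23420 gene symbols, 22976 (98.1%) matched GENCODE M21 (GRCm38), which gave coordinates and the genes on the opposite strand.

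Genes with enough counts by edgeR's filterByExpr (8141 genes) were scaled by trimmed mean of M-values (TMM) factors of 0.924 to 1.09. They were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. All 6 libraries entered 1 fit of group means, because 2 libraries per group leave 3 residual degrees of freedom, and no block was used. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 per comparison. The biological coefficient of variation was 33.0% and the prior degrees of freedom 8.20. Libraries of a group differed beyond counting noise, with chi-square per degree of freedom of 2.76 in YG+ pDCs, 11.9 in PBS pDCs and 5.66 in Sirpa+ DCs, so none was counted as a duplicate.

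Before the data were examined, 31 gene lists of cell type markers, immune and metabolic functions and RNA quality were fixed. The 24 with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Some genes are in more than 1 list. Named genes followed a rule fixed at the same time. It took the 10 largest rises and 10 largest falls among called genes with a mean of at least 20 CPM in the higher group and no overlap of the groups, without predicted genes and antigen receptor segments. It added the 4 members of each list with the smallest p, and Ptprc, Itgax, Sirpa, Siglech, Bst2, Ccr9 and Tcf4. Fewer are printed, from the top of each ranking. Some genes that this rule takes are not reported here. Principal components and Pearson correlations used the same log2 CPM. Shared control libraries were allowed for with 50 simulations of unchanged groups, and, after the data were seen, with 50 where Sirpa+ DCs kept their fitted levels and YG+ pDCs took those of PBS pDCs. Each gene was drawn independently, so changes that many genes share within a library were left out.

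The fit was tested on counts simulated for 8141 genes in YG+ pDCs against PBS pDCs, in 5 runs. Of the simulated genes that passed the filter, it called 2.90% of those changed 2-fold, 38.7% at 4-fold, 85.5% at 8-fold and 96.0% at 16-fold, and 0.0957% of unchanged genes. In a separate simulation, deeper than the real data and restricted to abundant genes, a true position of 0.3 was estimated at 0.312. That check does not cover the real depth or the less abundant genes. A shifted list had an adjusted p of 1.25e-27, and 0 of 23 other lists were called. Alternatives fixed in advance were other scalings, no filter, a filter at 10 CPM, DESeq2 1.42.0, limma-voom, glmTreat against a 1.5-fold change, a fit of the 4 libraries compared, a replicate block, each library left out in turn, an estimated correlation and fry. Restriction to genes with no gene on the opposite strand, removal of Rn45s, Malat1, Tsix and Xist, and a covariate for the share of reads in genes were added after the data were seen. Strand classes used genes with at least 20 counts over both libraries and a pseudocount of 0.5. Intervals of the added tests came from 2000 bootstrap draws. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Splits of the samples were not counted, since each group had 2 libraries.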

Results

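Gene-level read counts were examined for dendritic cells (DCs) sorted by flow cytometry from the mouse thymus. The 6 libraries formed 3 groups of 2. One group held plasmacytoid DCs (pDCs, gated on low CD11c and on B220) that carried yellow-green fluorescent microspheres (YG). These cells came from mice bearing MC38 tumours, a colon carcinoma line, whose tumours had received the microspheres 2 days before cells were isolated. The other groups held pDCs and Sirpa+ DCs (high CD11c, a conventional DC subset) from mice given PBS. The injected material, the YG gate and, as far as the labels tell, the tumour all separate the YG+ pDCs from the PBS pDCs, so that comparison does not tell them apart. Nothing in the labels says whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

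Total gene counts were 713966 and 565406 in the YG+ pDC libraries, 177844 and 413846 in the PBS pDC libraries, and 261136 and 525418 in the PBS Sirpa+ DC libraries. These were 0.842% to 3.36% of the uniquely placed reads, with the lowest share in PBS pDC replicate 1 (95% Wilson interval 0.838% to 0.846%). The ribosomal precursor transcript Rn45s took 12.7% and 10.6% of gene counts in the YG+ pDC libraries and 3.69% and 7.90% in the PBS pDC libraries. In the Sirpa+ DC libraries it took 7.05% and 9.39%. Tsix, which lies opposite to Xist, had 2.70 to 20.5 times the counts of Xist. Levels below are normalised read counts (CPM), given as mean ± SD of 2 libraries. The count of 0 allowed up to 4.20 to 16.9 CPM per library, and intervals and floors cover counting error only.

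Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.934 between the YG+ pDC libraries, 0.726 between the PBS pDC libraries and 0.855 between the Sirpa+ DC libraries. PBS pDC replicate 2 correlated more closely with the YG+ pDC libraries (0.863 and 0.897) than with PBS pDC replicate 1. The first principal component (51.1% of variance) parted Sirpa+ DCs from the pDC libraries, and the second (31.9%) had PBS pDC replicate 1 at one end. This library also differed from its partner by gene position. In genes with no annotated gene on the opposite strand, the median log2 count ratio of PBS pDC replicate 1 to replicate 2 was -1.80. It was -0.39 in genes with 20% to 50% of their exon length under an exon of the opposite strand, and -0.05 above 50%. Over the first and last of these classes the ratio went from -1.22 to -0.40 in Sirpa+ DCs and from 0.36 to 0.07 in YG+ pDCs. Values of overlapping genes are therefore uncertain, because the strand setting of the counting is not given in the sources used here.

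**Figure D1:**
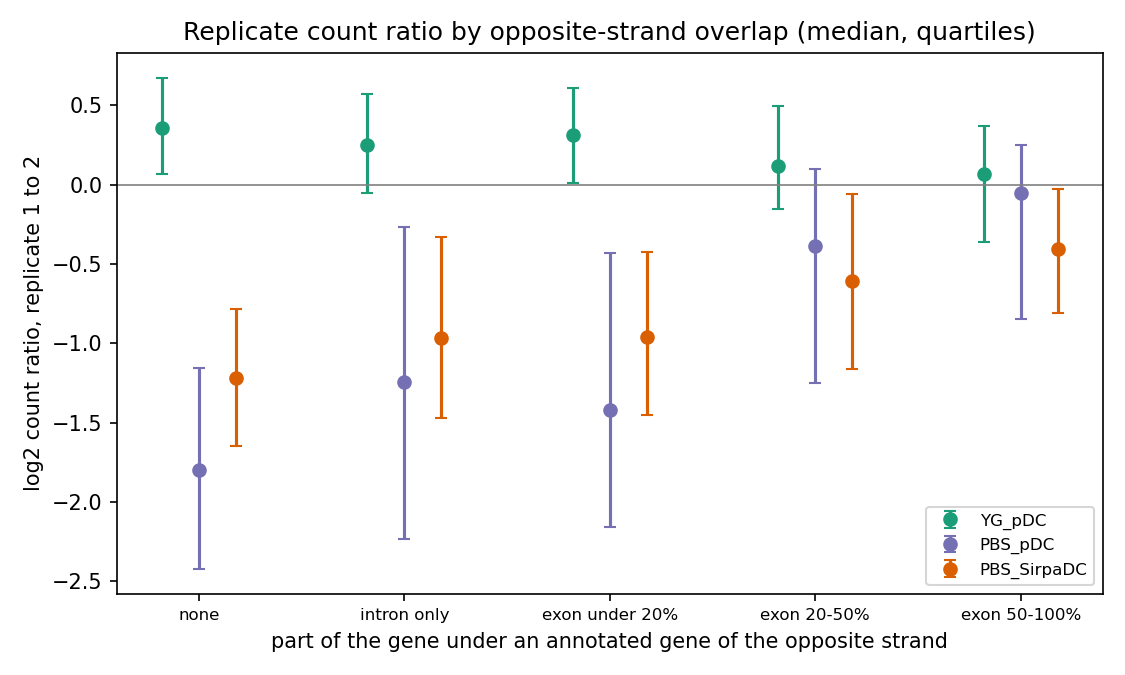
The vertical axis gives the log2 ratio of counts in replicate 1 to replicate 2 of each group, and the horizontal axis the part of a gene's exons under an annotated gene of the opposite strand. Points are medians over genes and bars are quartiles, and in PBS pDCs the median runs from -1.80 to -0.05.

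The pDCs and Sirpa+ DCs of PBS mice were compared to establish what set the subsets apart. Siglech, a pDC surface lectin (chromosome 7, 55768178 to 55778925, GRCm38), was 993 ± 92.6 CPM in pDCs and 45.2 ± 1.90 CPM in Sirpa+ DCs, a log2 fold change of 4.45 ± 0.49 (SE; adjusted p = 7.90e-04, edgeR quasi-likelihood test). The chemokine receptor gene Ccr9 was 789 ± 124 against 65.9 ± 8.57 CPM, and Tcf4, the transcription factor that maintains the pDC lineage, 543 ± 236 against 109 ± 4.15 CPM. Conversely, the actin-bundling gene Fscn1 (chromosome 5, 142960343 to 142973185) was 2454 ± 527 CPM in Sirpa+ DCs and 151 ± 30.1 CPM in pDCs, and the cytokine gene Il1b 579.9 ± 149.9 and 6.66 ± 0.399 CPM. Of 8141 genes tested, 931 passed a 5% false discovery rate, 370 higher in pDCs and 561 higher in Sirpa+ DCs.

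The pDC identity list was higher in pDCs, with a median log2 fold change of 3.04 (camera adjusted p = 1.60e-15, and adjusted p = 0.178 with an estimated correlation). Among 25 measured members 19 rose and 0 fell (21 and 0 adjusted over the list alone). Klk1 was 344 ± 45.2 against 0.997 ± 1.41 CPM and Atp1b1 361 ± 141 against 2.99 ± 4.23 CPM. Bst2, a surface protein used to mark pDCs, was 1399 ± 493 against 422 ± 52.0 CPM (adjusted p = 0.0302). B cell genes were also higher, with a median of 4.54 (3.54 with members at 0 in a group set to their bound, camera adjusted p = 1.58e-11, and adjusted p = 0.0584 with an estimated correlation). In all, 11 of 15 measured members rose and 0 fell, or 12 and 0 adjusted over the list alone. Ms4a1 was 78.2 ± 20.3 CPM in pDCs and 0 in Sirpa+ DCs (at least 19.2-fold higher), Fcrla 247 ± 47.9 against 4.11 ± 0.172 CPM and Cd79a, a part of the B cell receptor, 104 ± 32.9 against 4.11 ± 0.172 CPM. The T cell and thymocyte list was higher at a median of 2.92 (1.89 with members at 0 in a group set to their bound, camera adjusted p = 0.00212, and adjusted p = 0.178 with an estimated correlation). The test called 3 of 7 measured members higher and 0 lower (5 and 1 adjusted over the list alone). Cd8b1, a co-receptor chain, was 230.3 ± 44.2 against 4.11 ± 0.172 CPM and Lck, a T cell kinase, 61.7 ± 12.0 against 5.11 ± 1.24 CPM.

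Among the largest rises in pDCs were Cmya5, Ly6d, Olfr165, Olfr164, Mzb1, Dntt, Jakmip1, Bank1 and Il2rb, and all of these but Olfr164 were at 0 in both Sirpa+ DC libraries. Against a floor of 3 counts over the group, Ly6d, a marker of early B lineage cells, was at least 105-fold higher at 429 ± 115 CPM. Mzb1, an endoplasmic reticulum protein of plasma cells and pDCs, was at least 40.6-fold higher at 165 ± 1.09 CPM, and Dntt, the terminal nucleotidyl transferase, at least 34.7-fold at 141 ± 55.5 CPM. Among the largest falls were Olfr112, Adcy6, Anxa3, Olfr114, Mmp25, Olfr113, Slco5a1, Stab1 and Olfr109, each at 0 in both pDC libraries. Anxa3 (chromosome 5, 96793339 to 96845966) was at least 47.8-fold lower in pDCs and Adcy6 at least 88.6-fold. Olfr genes belong to a family of closely related receptors, so their counts are uncertain, as are those of Cmya5, Adcy6 and Stab1, which overlap an exon of the opposite strand.

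Lists of conventional DC function were lower in pDCs. Mature or migratory DC genes were lower, with a median of -2.86 (-2.75 with members at 0 in a group set to their bound, camera adjusted p = 4.89e-16, and adjusted p = 0.0584 with an estimated correlation). Of 22 measured members, 18 fell and 0 rose, against 22 and 0 adjusted over the list alone. Anxa3 was 0 against 244 ± 27.5 CPM, Cacnb3 7.54 ± 7.38 against 410.4 ± 89.8 CPM and the chemokine gene Ccl5 6.66 ± 0.399 against 195 ± 24.1 CPM. NF-kB and inflammatory genes were lower, with a median of -1.19 (camera adjusted p = 2.76e-06, and adjusted p = 0.178 with an estimated correlation). Among 22 measured members 10 fell and 1 rose (12 and 1 adjusted over the list alone). Cxcl16, a chemokine gene, was 38.5 ± 8.66 against 1079.8 ± 199 CPM and Ptgs2, a prostaglandin synthase gene, 3.19 ± 4.51 against 197 ± 9.16 CPM. Monocyte and macrophage genes were lower, with a median of -3.82 (camera adjusted p = 5.02e-06, and adjusted p = 0.339 with an estimated correlation). In all, 10 of 15 measured members fell and 0 rose, or 10 and 1 adjusted over the list alone. Csf1r, the receptor for macrophage colony-stimulating factor, was 18.5 ± 9.86 against 675 ± 182 CPM and the complement gene C1qa 8.69 ± 5.75 against 614 ± 234 CPM. MHC class II presentation genes were lower, with a median of -0.99 (camera adjusted p = 0.00155, and adjusted p = 0.339 with an estimated correlation). The test called 5 of 13 measured members lower and 0 higher (6 and 0 adjusted over the list alone). H2-Eb1 was 1183 ± 176 against 6416 ± 1306 CPM and the protease gene Ctss 257 ± 29.5 against 1119 ± 410.3 CPM. Phagocytosis and lysosome genes were lower, with a median of -1.42 (camera adjusted p = 6.08e-04, and adjusted p = 0.339 with an estimated correlation). Of 23 measured members, 8 fell and 1 rose, against 14 and 3 adjusted over the list alone. The lysosomal protease gene Ctsd was 106 ± 39.1 against 708 ± 253 CPM and the receptor kinase gene Axl 87.5 ± 2.60 against 519 ± 154 CPM.

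Sirpa+ conventional DC (cDC2) genes were lower, with a median of -1.22 (camera adjusted p = 0.00594, and adjusted p = 0.275 with an estimated correlation). Among 18 measured members 7 fell and 1 rose (10 and 4 adjusted over the list alone). The gate marker Sirpa was 259 ± 86.0 against 662 ± 122 CPM (adjusted p = 0.0754), and Itgax, which encodes CD11c, 213 ± 75.4 against 524 ± 125 CPM (adjusted p = 0.0988). Conventional DC type 1 (cDC1) genes were lower, with a median of -1.74 (camera adjusted p = 0.0253, and adjusted p = 0.267 with an estimated correlation). In all, 6 of 12 measured members fell and 2 rose, or 7 and 2 adjusted over the list alone. Itgae had a log2 fold change of -3.72 ± 0.56 (SE, 139 ± 11.6 CPM in Sirpa+ DCs) and Clec9a was 38.5 ± 27.4 against 279 ± 59.6 CPM, whereas Irf8, a transcription factor that pDCs also express, was higher at 1438 ± 338 against 299 ± 51.3 CPM. Interferon-stimulated genes were lower, with a median of -0.83 (camera adjusted p = 0.00155, and adjusted p = 0.339 with an estimated correlation). The test called 6 of 28 measured members lower and 1 higher (6 and 1 adjusted over the list alone). Isg15 was 7.82 ± 2.03 against 77.0 ± 1.12 CPM. Cholesterol and lipid genes were lower, with a median of -0.97 (camera adjusted p = 0.00115, and adjusted p = 0.178 with an estimated correlation). Of 19 measured members, 4 fell and 0 rose, against 6 and 0 adjusted over the list alone. The fatty acid binding protein gene Fabp5 was 3.47 ± 4.91 against 212 ± 109 CPM and the lipid droplet gene Plin2 6.94 ± 9.82 against 142 ± 9.99 CPM. Immune checkpoint and tolerance genes were lower, with a median of -0.63 (camera adjusted p = 0.0343, and adjusted p = 0.267 with an estimated correlation). Among 15 measured members 5 fell and 0 rose (6 and 2 adjusted over the list alone). Tgfbi, a matrix protein gene induced by TGF-beta, was 9.85 ± 4.11 against 967 ± 392 CPM. Apoptosis and p53 genes were lower, with a median of -0.80 (camera adjusted p = 0.0258, and adjusted p = 0.515 with an estimated correlation). In all, 4 of 18 measured members fell and 0 rose, or 4 and 0 adjusted over the list alone. Cdkn1a, a cell cycle inhibitor, was 11.6 ± 16.4 against 342 ± 23.4 CPM. Glycolysis and hypoxia genes were lower, with a median of -0.23 (camera adjusted p = 0.0499, and adjusted p = 0.434 with an estimated correlation). The test called 3 of 17 measured members lower and 0 higher (3 and 0 adjusted over the list alone). Hk2, a hexokinase gene, was 63.7 ± 17.9 against 403 ± 1.94 CPM. Immediate early and stress genes were lower, with a median of -0.59 (camera adjusted p = 0.0499, and adjusted p = 0.275 with an estimated correlation). Of 21 measured members, 4 fell and 1 rose, against 5 and 1 adjusted over the list alone.

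Camera called 16 of 24 lists here, 0 with an estimated correlation, and fry, a rotation test of direction, called 13. Lists not called were MHC class I presentation (-0.31), Toll-like receptor and type I interferon production (0.45), trafficking and adhesion (0.16, with 5 members higher and 4 lower), oxidative phosphorylation (-0.19), unfolded protein response (0.31), cytosolic ribosomal proteins (0.24), nuclear-retained transcripts (0.05) and cell cycle, whose median was 0.01 and mean -0.10. Without Sirpa+ DC replicate 1 the gene count was 316 and without replicate 2 it was 214, with 17 and 29 of 74 called genes among the examined set losing their call. List calls lost without PBS pDC replicate 2 were cDC1 (adjusted p = 0.143), T cell (0.0681) and immune checkpoint (0.149). The checkpoint list was lost also without PBS pDC replicate 1 (0.0693) and Sirpa+ DC replicate 2 (0.0867), and the apoptosis list without the same libraries (0.243 and 0.0796). The glycolysis and immediate early lists were each lost whichever of the 6 libraries was left out, at adjusted p from 0.0518 to 0.284. MHC class I genes were called without Sirpa+ DC replicate 1 (0.0469), and ribosomal proteins without PBS pDC replicate 2 (0.00249) or Sirpa+ DC replicate 2 (0.00581). The gene count was 580 in a fit of these 4 libraries and 1644 with the share of reads in genes as a covariate, which was added after the data were seen.

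**Figure D2:**
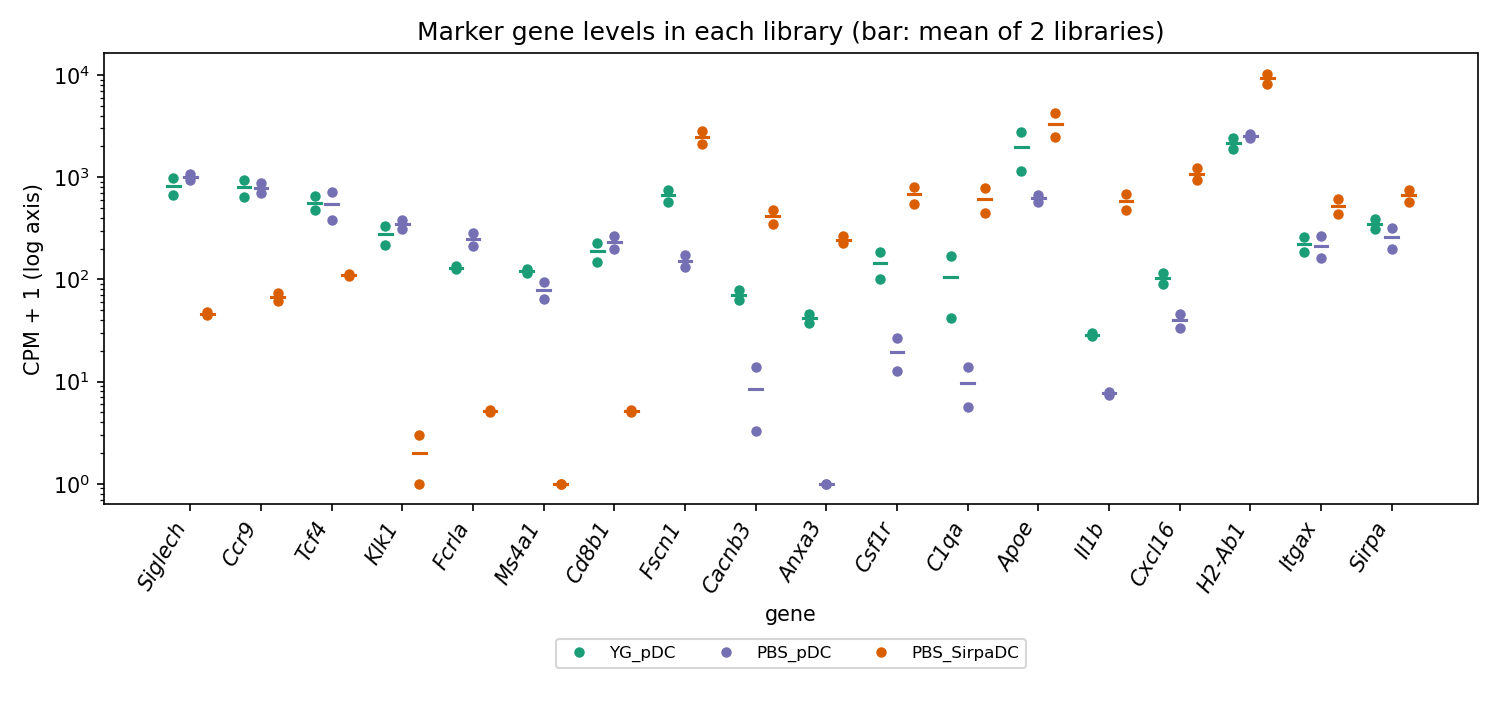
Each point is 1 library and each bar the mean of 2, and the vertical axis is CPM plus 1 on a log axis. Siglech was 824 ± 218 CPM in YG+ pDCs and 993 ± 92.6 CPM in PBS pDCs, while Fscn1 was 663 ± 128 and 151 ± 30.1 CPM.

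The central comparison asked how thymic pDCs that carried microspheres injected in a tumour differed from pDCs of PBS mice. For Ccr9 and Tcf4 the difference was smaller than the spread between replicates, and for Siglech it was smaller than that of the YG+ pDCs only. Siglech was 824 ± 218 CPM in YG+ pDCs and 993 ± 92.6 CPM in PBS pDCs, Ccr9 789.6 ± 217 and 789 ± 124 CPM, and Tcf4 562 ± 126 and 543 ± 236 CPM. Bst2 was 845 ± 148 and 1399 ± 493 CPM (adjusted p = 0.564). Several genes that were high in Sirpa+ DCs had higher means in YG+ pDCs. Fscn1 was 663 ± 128 against 151 ± 30.1 CPM, a log2 fold change of 2.15 ± 0.46 (SE; adjusted p = 0.254). Csf1r was 142 ± 59.3 against 18.5 ± 9.86 CPM (adjusted p = 0.235) and Apoe, a lipid carrier gene, 1956 ± 1161 against 619 ± 71.1 CPM (adjusted p = 0.315). No single gene passed: the edgeR quasi-likelihood test called 0 of 8141 genes, with 929 at an unadjusted p under 0.05 (382 higher and 547 lower, 407 by chance) and a smallest adjusted p of 0.235. limma-voom also called 0, and DESeq2 called 111, 16 higher and 95 lower. With no filter on low counts edgeR called 141, 46 higher and 95 lower.

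Camera called 7 of 24 lists, all higher in YG+ pDCs. The monocyte and macrophage list had a median log2 fold change of 2.44 (camera adjusted p = 1.66e-04, and adjusted p = 0.740 with an estimated correlation). By member, 9 of its 15 measured members rose and 0 fell adjusted over the list alone, and 0 passed over all genes. C1qa was 105 ± 90.1 against 8.69 ± 5.75 CPM, with a wide spread between the YG+ pDC libraries. The mature or migratory DC list had a median log2 fold change of 1.39 (1.24 with members at 0 in a group set to their bound, camera adjusted p = 2.13e-08, and adjusted p = 0.182 with an estimated correlation). Here 10 of its 22 measured members rose and 0 fell adjusted over the list alone, and 0 passed over all genes. Anxa3 was 40.6 ± 5.81 CPM and 0 (at least 7.98-fold higher), Cacnb3, a calcium channel subunit gene, 69.4 ± 10.7 against 7.54 ± 7.38 CPM and Marcksl1 59.8 ± 8.72 against 11.3 ± 6.94 CPM. The NF-kB and inflammatory list had a median log2 fold change of 0.59 (camera adjusted p = 2.92e-04, and adjusted p = 0.291 with an estimated correlation). In this list 2 of its 22 measured members rose and 0 fell adjusted over the list alone, and 0 passed over all genes. Tnfaip2 was 51.8 ± 20.1 against 3.47 ± 4.91 CPM, and Ptgs2 had a log2 fold change of 3.95 ± 1.00 (SE; adjusted p = 0.315). The cholesterol and lipid list had a median log2 fold change of 0.54 (camera adjusted p = 0.0120, and adjusted p = 0.291 with an estimated correlation). There 5 of its 19 measured members rose and 0 fell adjusted over the list alone, and 0 passed over all genes. Nr1h3, an oxysterol receptor gene, was 23.0 ± 7.21 against 3.19 ± 4.51 CPM and the scavenger receptor gene Cd36 27.8 ± 6.40 against 1.16 ± 1.64 CPM.

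The cDC2 list had a median log2 fold change of 0.77 (0.71 with members at 0 in a group set to their bound, camera adjusted p = 0.0154, and adjusted p = 0.511 with an estimated correlation). Only 1 of its 18 measured members rose adjusted over the list alone, and 0 passed over all genes. Tnip3 was 9.39 ± 0.626 against 0 CPM and Sirpa 349 ± 60.8 against 259 ± 86.0 CPM. The immediate early and stress list had a median log2 fold change of 0.44 (camera adjusted p = 0.00993, and adjusted p = 0.291 with an estimated correlation). The apoptosis and p53 list had a median log2 fold change of 0.52 (camera adjusted p = 0.0120, and adjusted p = 0.794 with an estimated correlation). In these lists 0 of 21 and 0 of 18 measured members passed over all genes or adjusted over the list alone. The stress-induced factor Atf3 was 72.1 ± 31.1 against 13.6 ± 10.2 CPM and Pmaip1, a pro-apoptotic p53 target, 157 ± 27.7 against 58.5 ± 28.6 CPM. The pDC identity list was not called (-0.11, camera adjusted p = 0.0979, and adjusted p = 0.844 with an estimated correlation), and 0 of its 25 measured members passed. Its smallest p-values were those of Smim5 (92.5 ± 23.5 against 246 ± 112 CPM), Ly6c2 (225 ± 33.8 against 475 ± 221 CPM) and Lefty1 (34.0 ± 20.3 against 83.4 ± 9.69 CPM). B cell genes were not called either (-0.16, camera adjusted p = 0.538, and adjusted p = 0.844 with an estimated correlation), with Fcrla at 129 ± 5.23 against 247 ± 47.9 CPM.

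Of the phagocytosis and lysosome list, 6 of 23 members rose and 1 fell adjusted over the list alone, 0 passed over all genes, and the list was not called (0.30, camera adjusted p = 0.0701, and adjusted p = 0.844 with an estimated correlation). Ctsd was 374 ± 111 against 106 ± 39.1 CPM, and the apoptotic cell receptor gene Mertk 40.3 ± 44.3 against 0 CPM. In the immune checkpoint and tolerance list (0.48, camera adjusted p = 0.111, and adjusted p = 0.511 with an estimated correlation), 0 passed over all genes and 1 rose adjusted over the list alone, which was Tgfbi at 88.5 ± 13.9 against 9.85 ± 4.11 CPM. Interferon-stimulated genes had a median of 0.08 (camera adjusted p = 0.708, and adjusted p = 0.879 with an estimated correlation), with Isg15 at 26.0 ± 8.93 against 7.82 ± 2.03 CPM. MHC class II genes had a median of 0.04 (camera adjusted p = 0.630, and adjusted p = 0.879 with an estimated correlation), with Ctss at 531 ± 88.6 against 257 ± 29.5 CPM. The other lists not called were cDC1 (0.44, or 0.39 with members at 0 set to their bound), Toll-like receptor and interferon production (0.02), trafficking and adhesion (0.23), glycolysis (0.15), unfolded protein response (0.12), cell cycle (0.43), T cell (0.55), ribosomal proteins (0.16) and nuclear-retained transcripts (0.27). Medians and means differed in sign for MHC class I (-0.01 and 0.13) and for oxidative phosphorylation (0.11 and -0.03).

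Genes with lower values in YG+ pDCs mostly overlapped a gene of the opposite strand. At an unadjusted p under 0.05 by edgeR, 547 genes were lower and 382 higher. Among genes matched to the annotation, an exon of the opposite strand lay over 73.9% of those lower, 24.3% of those higher and 36.5% of those tested. The same held for 74 of the 95 genes lower by DESeq2 and 4 of the 16 higher. PBS pDC replicate 1 kept more of its counts in such genes. Its median log2 ratio to replicate 2 was -0.05 above 50% overlap and -1.80 with no opposite-strand gene. The excess of overlapping genes may therefore come from that library rather than from the YG+ pDCs, and the 2 were not told apart. Among genes with no gene on the opposite strand, an alternative chosen after the data were seen, camera called the mature DC (adjusted p = 2.73e-08), macrophage (0.00474) and cholesterol (0.00474) lists higher and the pDC identity list lower (0.0281), and the NF-kB list was at 0.0578. Without PBS pDC replicate 2, 870 genes passed (230 higher and 640 lower) and the macrophage (0.141), immediate early (0.141), cDC2 (0.247) and cholesterol (0.308) calls were lost. Without PBS pDC replicate 1 the gene count was 3, pDC identity was lower (0.0278), phagocytosis (0.00245) and ribosomal proteins (3.95e-04) were higher and apoptosis was lost (0.282). Without YG+ pDC replicate 2 the count was 14, with pDC identity lower (0.00865) and phagocytosis (7.00e-04) and cell cycle (0.0190) higher. Without YG+ pDC replicate 1 apoptosis was lost (0.0595), and without Sirpa+ DC replicate 1 or 2, which share the fit, phagocytosis was called (0.0117 and 0.0484). The mature DC and NF-kB calls held without each library in turn. With an estimated correlation camera called 0 lists, and fry called 3 (mature DC, NF-kB and immediate early).

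**Figure D3:**
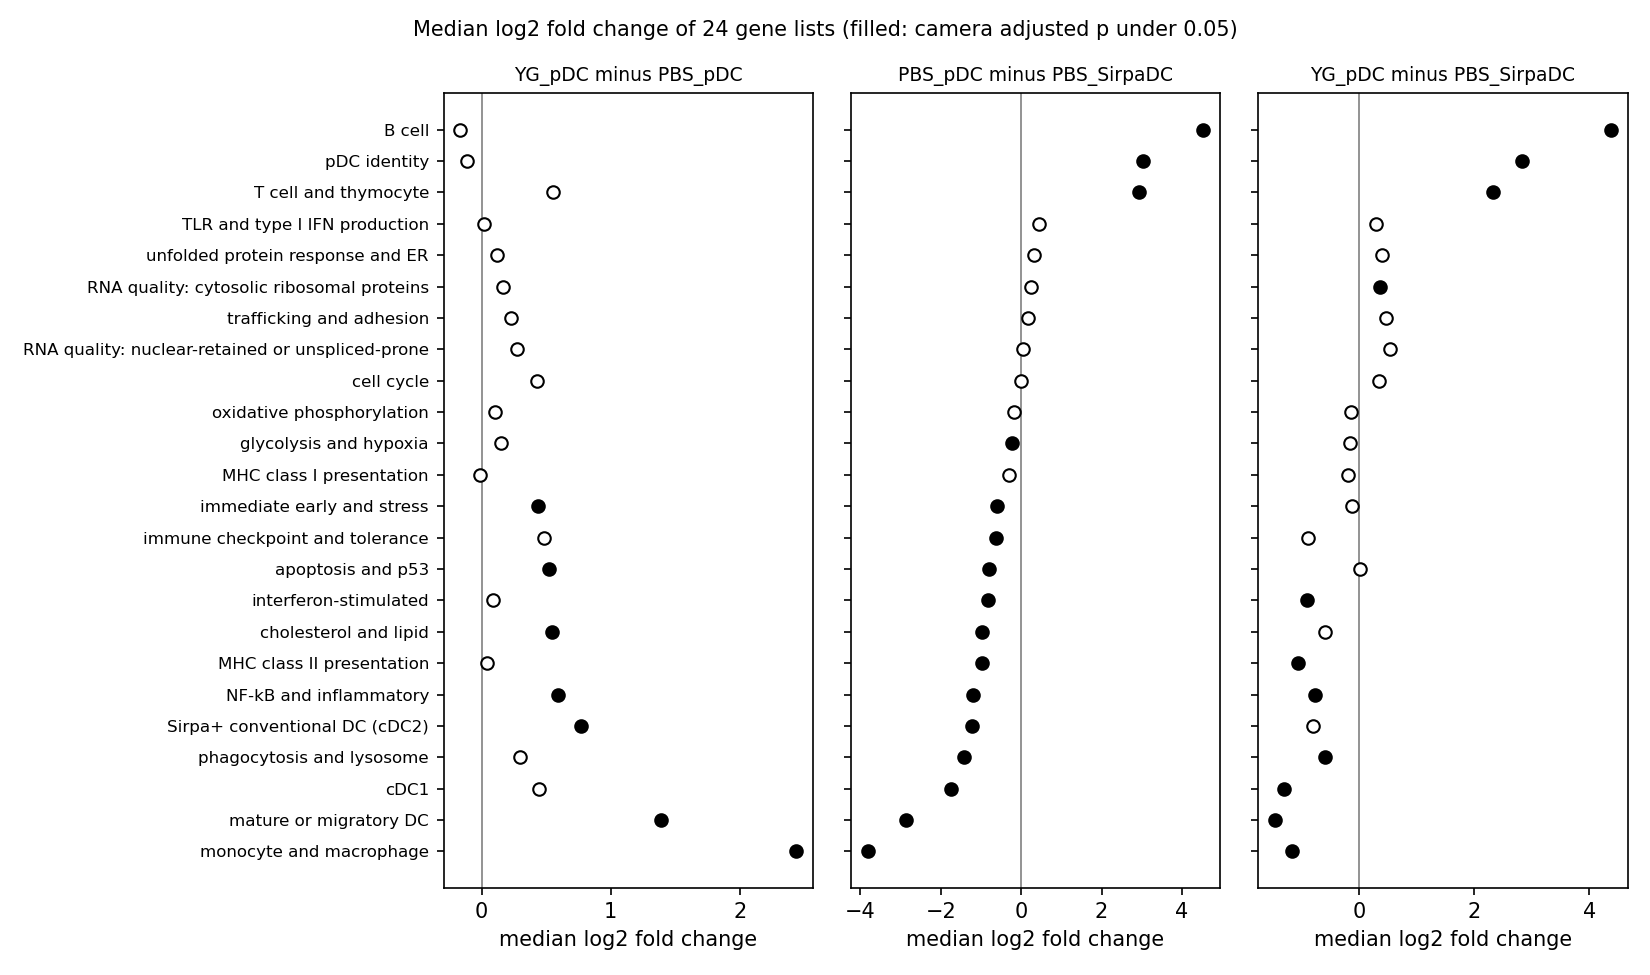
Each point is the median log2 fold change over the measured members of 1 of 24 gene lists, in the 3 comparisons, and filled points are lists that camera called with a preset correlation. The monocyte and macrophage list stands at 2.44 in YG+ pDCs against PBS pDCs and at -3.82 in PBS pDCs against Sirpa+ DCs.

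YG+ pDCs were also set against PBS Sirpa+ DCs, a comparison in which both cell type and treatment differ. Siglech was 824 ± 218 against 45.2 ± 1.90 CPM, a log2 fold change of 4.19 ± 0.49 (SE; adjusted p = 0.00137), and Klk1 275 ± 82.4 against 0.997 ± 1.41 CPM. Bst2 was 845 ± 148 against 422 ± 52.0 CPM (adjusted p = 0.204). The cytokine gene Il1b was lower at 27.7 ± 1.37 against 579.9 ± 149.9 CPM. The edgeR test called 583 of 8141 genes, 250 higher and 333 lower in YG+ pDCs. The pDC identity list was higher, at a median of 2.83 (camera adjusted p = 1.55e-15, and adjusted p = 0.248 with an estimated correlation). Among 25 measured members 16 rose and 0 fell (20 and 0 adjusted over the list alone). B cell genes were higher, at a median of 4.37 (4.05 with members at 0 in a group set to their bound, camera adjusted p = 2.99e-11, and adjusted p = 0.0615 with an estimated correlation). In all, 11 of 15 measured members rose and 0 fell, or 12 and 0 adjusted over the list alone. Ms4a1 was 119.8 ± 7.42 CPM and 0 (at least 29.5-fold higher). T cell and thymocyte genes were higher, at a median of 2.32 (camera adjusted p = 2.55e-04, and adjusted p = 0.209 with an estimated correlation). The test called 3 of 7 measured members higher and 0 lower (6 and 0 adjusted over the list alone). Cd8b1 was 186 ± 55.1 against 4.11 ± 0.172 CPM. Cytosolic ribosomal protein genes had a median of 0.35 (camera adjusted p = 0.00825, and adjusted p = 0.699 with an estimated correlation), with 0 of 75 members passing over all genes or adjusted over the list alone.

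Mature or migratory DC genes were lower, at a median of -1.47 (camera adjusted p = 2.52e-11, and adjusted p = 0.0615 with an estimated correlation). Of 22 measured members, 8 fell and 0 rose, against 17 and 0 adjusted over the list alone. Ccl17, a chemokine gene, was 2.30 ± 0.721 against 73.2 ± 16.1 CPM and Anxa3 40.6 ± 5.81 against 244 ± 27.5 CPM. NF-kB and inflammatory genes were lower, at a median of -0.77 (camera adjusted p = 9.78e-04, and adjusted p = 0.248 with an estimated correlation). Among 22 measured members 6 fell and 0 rose (8 and 0 adjusted over the list alone). Cxcl16 was 102 ± 17.2 against 1079.8 ± 199 CPM. MHC class II presentation genes were lower, at a median of -1.08 (camera adjusted p = 0.00153, and adjusted p = 0.451 with an estimated correlation). In all, 3 of 13 measured members fell and 0 rose, or 6 and 0 adjusted over the list alone. H2-Ab1 was 2139 ± 358 against 9239 ± 1499 CPM and H2-Eb1 1603 ± 194 against 6416 ± 1306 CPM. Monocyte and macrophage genes were lower, at a median of -1.17 (camera adjusted p = 9.78e-04, and adjusted p = 0.522 with an estimated correlation). The test called 2 of 15 measured members lower and 0 higher (7 and 1 adjusted over the list alone). Csf1r was 142 ± 59.3 against 675 ± 182 CPM and C1qa 105 ± 90.1 against 614 ± 234 CPM. Conventional DC type 1 (cDC1) genes were lower, at a median of -1.31 (camera adjusted p = 0.0125, and adjusted p = 0.248 with an estimated correlation). Of 12 measured members, 4 fell and 1 rose, against 7 and 2 adjusted over the list alone. Itgae was 19.7 ± 0.0125 against 139 ± 11.6 CPM, and Irf8 was higher at 1338 ± 312 against 299 ± 51.3 CPM. Interferon-stimulated genes were lower, at a median of -0.91 (camera adjusted p = 9.78e-04, and adjusted p = 0.451 with an estimated correlation). Among 28 measured members 1 fell and 0 rose (3 and 0 adjusted over the list alone). Oas2 was 18.9 ± 9.02 against 90.7 ± 15.4 CPM. Phagocytosis and lysosome genes were lower, at a median of -0.61 (camera adjusted p = 0.0116, and adjusted p = 0.527 with an estimated correlation). In all, 1 of 23 measured members fell and 0 rose, or 3 and 1 adjusted over the list alone. Lgals3, a galectin gene, was 51.5 ± 4.57 against 252 ± 92.5 CPM.

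Among the largest rises were Ly6d, Ms4a1, Cmya5, Mzb1, Jakmip1, Pou2af1, Dntt, Bank1 and Amigo2, each at 0 in both Sirpa+ DC libraries. Pou2af1, a B cell transcriptional co-activator, was 102 ± 0.606 CPM and Ly6d 329 ± 58.3 CPM. The largest falls were Acan, Olfr114, Mmp1b, Olfr116, Dcstamp, Cpa3, Olfr115, Olfr113, Olfr112 and Sulf1. Dcstamp, a cell fusion gene of myeloid cells, was 0 against 48.4 ± 9.29 CPM (at least 20.5-fold lower), and Olfr112 18.8 ± 1.25 against 1009 ± 511 CPM. Lists not called were cDC2 (-0.81), trafficking and adhesion (0.46), immune checkpoint (-0.90), cholesterol and lipid (-0.60), MHC class I (-0.20), Toll-like receptor and interferon production (0.28), glycolysis (-0.16), oxidative phosphorylation (-0.15), unfolded protein response (0.39), cell cycle (0.34) and nuclear-retained transcripts (0.53). Immediate early and apoptosis lists, with medians of -0.13 and 0.01, were not called, and their means were 0.00 and -0.18.

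Of the YG+ pDC against Sirpa+ DC calls, the gene count was 69 without Sirpa+ DC replicate 1, 115 without replicate 2, 271 without YG+ pDC replicate 1 and 176 without replicate 2. It was 1487 without PBS pDC replicate 1 and 1467 without replicate 2, libraries that are in neither group but enter the filter, the scaling and the estimate of spread. A fit of the 4 libraries compared called 1480 genes, and no filter on low counts gave 894. Without YG+ pDC replicate 2 the macrophage (0.300) and phagocytosis (0.127) lists were lost and trafficking was called (0.0436). Without Sirpa+ DC replicate 2 the macrophage (0.204), phagocytosis (0.134), cDC1 (0.0551) and interferon-stimulated (0.0551) lists were lost. Ribosomal protein genes were lost without YG+ pDC replicate 1 (0.0581) or Sirpa+ DC replicate 1 (0.265), where cDC2 was called (0.0450 and 0.0354), and cholesterol was called without YG+ pDC replicate 1 (0.0243). With an estimated correlation camera called 0 lists (11 with the preset one), and fry called 6.

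Over the 931 genes that differed between PBS pDCs and Sirpa+ DCs, YG+ pDCs lay a median 0.299 of the way from PBS pDCs to Sirpa+ DCs on the log2 scale. The median was 0.403 for the 561 genes higher in Sirpa+ DCs and 0.104 for the 370 higher in pDCs, and 90.9% and 72.4% of these had values on the Sirpa+ DC side of the PBS pDC level. In 50 simulations where YG+ pDCs did not differ from PBS pDCs but shared them as controls, these were 0.0769 (0.0615 to 0.0925), 0.0892 (0.0615 to 0.117), 0.0670 (0.0455 to 0.0898), 61.5% and 64.1%. These simulations called a mean of 1693 genes between PBS pDCs and Sirpa+ DCs, more than the real data, and their PBS pDC libraries differed less from each other, by a median absolute log2 difference of 0.56 against 0.79, so they may understate the pull of the shared controls. Fscn1, Csf1r and Cacnb3 lay between the PBS groups (663, 142 and 69.4 CPM). The MHC class II gene H2-Ab1, chosen after its values were seen, was 2139 ± 358 CPM in YG+ pDCs, 2534 ± 141 CPM in PBS pDCs and 9239 ± 1499 CPM in Sirpa+ DCs. Both differences were measured against the same PBS pDC libraries. Their correlation across genes was 0.605, against 0.556 in 50 simulations of unchanged groups that shared those libraries (0.534 to 0.582). The covariance was 1.03, 0.818 above the simulated 0.215. The same sign was seen in 66.1% of genes, against 68.4% in simulations. In these 50 simulations Sirpa+ DCs did not differ from PBS pDCs either, unlike in the data. Their values may therefore not be those of unchanged YG+ pDCs, and they decide nothing here. That 0 genes were called in both comparisons was fixed by the 0 calls in YG+ pDCs against PBS pDCs. With 2 control libraries the controls could not be split, so part of the covariance excess may come from them. Without PBS pDC replicate 2 the median position was 0.628, and the medians of the genes higher in Sirpa+ DCs and in pDCs no longer lay apart (0.633 and 0.619). With any other library left out these were 0.332 to 0.463 and 0.0524 to 0.151, and the overall median was 0.233 to 0.379.

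Markers of other cell types and of RNA quality with fewer than 5 measured members were counted but not tested as lists. The measured members were 3 NK cell, 3 granulocyte, 2 erythroid and platelet, 3 epithelial, 4 stroma and endothelium, 2 sex-linked and 0 mitochondrially encoded genes. In pDCs against Sirpa+ DCs of PBS mice, 1 of the NK cell genes rose and 0 fell (2 and 0 adjusted over the list alone), 0 of the granulocyte genes rose and 0 fell (1 and 2 adjusted over the list alone), 0 of the epithelial genes rose and 2 fell (0 and 2 adjusted over the list alone) and 2 of the stroma and endothelium genes rose and 0 fell (3 and 0 adjusted over the list alone). In YG+ pDCs against Sirpa+ DCs, 1 of the NK cell genes rose and 0 fell (1 and 0 adjusted over the list alone), 1 of the granulocyte genes rose and 1 fell (1 and 1 adjusted over the list alone), 0 of the erythroid and platelet genes rose and 1 fell (0 and 1 adjusted over the list alone), 0 of the epithelial genes rose and 1 fell (0 and 1 adjusted over the list alone), 2 of the stroma and endothelium genes rose and 0 fell (2 and 0 adjusted over the list alone) and 0 of the sex-linked genes rose and 0 fell (1 and 0 adjusted over the list alone). In YG+ pDCs against PBS pDCs 0 members passed over all genes or adjusted over the list alone. Among the genes given values above, Adcy6, Atp1b1, Ccr9, Cdkn1a, Csf1r, Cxcl16, Il1b and Tnfaip2 overlap an annotated exon of the opposite strand, so their values are uncertain.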

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

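The test of library depth in this part was chosen after its result was seen, while the strand-pair and genomic DNA tests were set down before theirs, when some class medians and olfactory receptor counts had been seen. Reads in no annotated gene, which no comparison uses, made up 96.6% and 97.4% of uniquely placed reads in YG+ pDCs, 99.2% and 97.9% in PBS pDCs, and 98.9% and 97.7% in Sirpa+ DCs. These values were picked out because they lie above the limit that a count of 0 allows in every library.

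In PBS pDC replicate 1, the library with the largest share of such reads, genes under a gene of the opposite strand kept more of their counts. A difference in depth alone would lower all classes alike, yet the median log2 ratio to replicate 2 was 1.75 higher where at least 50% of the exon length lay under an opposite-strand exon than with no opposite gene (95% bootstrap interval 1.43 to 1.93). Genomic DNA spread evenly over both strands would fill silent genes, but 1441 olfactory, vomeronasal and keratin-associated genes held 0.0199 to 0.0402 of the counts that it would give. Counting of the strand opposite to transcription may contribute. Log2 fold changes of PBS pDCs against Sirpa+ DCs had a Spearman rho of 0.549 over 360 opposite-strand partners. Over 2070 neighbours that do not overlap it was 0.362, a difference of 0.188 (95% bootstrap interval 0.0987 to 0.275, shuffled partners 0.00279). A pair could enter from each of its genes, so this interval may be too narrow. The fold changes also hold the shift of overlapping genes in PBS pDC replicate 1, so the higher rho may partly restate it. Opposite-strand counting stays a hypothesis, since neither the strand setting nor whether the kit marks strand is given in the sources used here. Reads from introns and a biological cause were not tested. Tsix had 20.5 times the counts of Xist in PBS pDC replicate 1, where 0.842% of uniquely placed reads lay in genes. In YG+ pDC replicate 1, where 3.36% did, it had 2.70 times. Such counting could affect the counts of all genes in every library, not only those of overlapping genes.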

How the results depend on the processing

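The tests restricted to genes with no opposite-strand gene, the removal of 4 abundant transcripts and the covariate were chosen after the data were seen, and the other alternatives were planned. YG+ pDCs against PBS pDCs gave 0 genes by edgeR under each scaling, the 10 CPM filter (which left 10766 genes, more than filterByExpr), glmTreat, the 4-library fit and the 3 added alternatives. They gave 141 with no filter, 111 by DESeq2, which left 6313 adjusted p-values undefined, and 0 to 870 with 1 library left out. The highest count came without PBS pDC replicate 2. PBS pDCs against Sirpa+ DCs gave 926 to 1003 genes under other scalings, 580 in the 4-library fit, 1644 with the covariate, and 214 (without Sirpa+ DC replicate 2) to 1297 with 1 library left out. YG+ pDCs against Sirpa+ DCs gave 600 to 635 under other scalings, 894 with no filter, 1480 in the 4-library fit, and 69 (without Sirpa+ DC replicate 1) to 1487 (without PBS pDC replicate 1). A fit that leaves a group with 1 library takes that library to vary like the others. Under each scaling 0 examined genes lost their call in these comparisons, and 0 of them changed sign where called. In YG+ pDCs against Sirpa+ DCs, 1 examined gene gained a call with relative log expression scaling and 1 with total count scaling. Some genes called in the PBS comparison without PBS pDC replicate 1 or replicate 2 had the opposite sign in the main fit. In YG+ pDCs against Sirpa+ DCs, so did 4 of the 868 genes called with the covariate. Where counts moved, the cause was not tested.

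With an estimated correlation camera called 0 lists in each comparison. Counts of lists below take in lists not called with the preset correlation and all libraries. In YG+ pDCs against PBS pDCs, where camera called 7 lists, fry called 3, and camera 4 with opposite-strand genes left out and 3 (without PBS pDC replicate 2) to 10 with 1 library left out. Against Sirpa+ DCs camera called 11, fry 6, and camera with 1 library left out 7 (without Sirpa+ DC replicate 2) to 12. In the PBS comparison these were 16, 13 and 12 to 15. The median position of YG+ pDCs was 0.233 to 0.628 with 1 library left out, highest without PBS pDC replicate 2. DESeq2 called 45 genes the same way in both comparisons against PBS pDCs, 16 higher (0.996 for independent lists) and 29 lower (4.01). In YG+ pDCs against PBS pDCs, an exon of the opposite strand lay over 74 of its 95 lower genes and 4 of its 16 higher. Such genes among the 29 were not counted, so the shift of overlapping genes in PBS pDC replicate 1 may enter their excess. The values for independent lists take all 8141 genes, though DESeq2 left 6313 adjusted p-values undefined in YG+ pDCs against PBS pDCs, so they may be too low. They also leave out the shared PBS pDC libraries. Simulations that share these libraries gave 0 and 0.0800, but called a mean of 0.240 genes in YG+ pDCs against PBS pDCs. They also had less spread between PBS pDC libraries than the data, so they do not settle the part of these libraries. The mean correlation between PBS pDC and Sirpa+ DC libraries was 0.470 at a prior count of 0.5, 0.539 at 2. With the replicate block, counts were 0, 942 and 635 genes, in the order of the comparisons above. Deviations of same-numbered libraries correlated at -0.121, 0.298 and -0.0990, so the numbers were not taken to pair samples, which stays open for the PBS groups. The simulated fit called 2.90% of genes changed 2-fold, and whether depth, spread or the number of libraries limits this was not tested.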

Other observations

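All tests in this part, and the genes described, were chosen after their values were seen. Olfactory receptor genes of different chromosomes went opposite ways between PBS pDCs and Sirpa+ DCs. On chromosome 17, between 37445480 and 37627199 (GRCm38, GENCODE M21), Olfr108, Olfr109 and Olfr111 to Olfr116 were higher in Sirpa+ DCs, with adjusted p from 6.91e-04 to 0.0452 by the edgeR quasi-likelihood test. Olfr112 was 1009 ± 511 CPM there, 0 in PBS pDCs and 18.8 ± 1.25 CPM in YG+ pDCs. On chromosome 16, between 19284104 and 19522266, Olfr164, Olfr165 and Olfr167 were higher in PBS pDCs. Olfr164 was 1766 ± 822 CPM in PBS pDCs, 1.99 ± 2.82 CPM in Sirpa+ DCs and 411 ± 163 CPM in YG+ pDCs (adjusted p = 0.315 against PBS pDCs). Olfr165 was 219 ± 149.8 CPM, 0 and 53.9 ± 22.5 CPM (adjusted p = 0.315). These genes have no annotated gene on the opposite strand. Reads not placed uniquely stay out of the gene counts, so values of related receptors may be too low and are uncertain. No explanation was tested.

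Transcripts of macrophages, mature DCs and inflammation had higher list medians in YG+ pDCs than in PBS pDCs. The low gene counts of PBS pDC replicate 1 do not account for this alone, since 6 of 7 called lists were still called higher without that library, though by camera with its preset correlation, while 0 lists were called with an estimated one. Sirpa+ DCs among the YG+ pDCs may contribute, although the gate on low CD11c should remove them: 203 other genes high in Sirpa+ DCs reached a median 19.4% and 11.8% of the way to their Sirpa+ DC level in the YG+ libraries and 31 list members 24.8% and 17.2%, ratios of 0.781 and 0.685 (95% bootstrap bounds 0.543 to 1.56). Whether they are the only source cannot be told apart. Of 17 abundant genes, 5.88% (1, Olfr112) lay below 50% of the median share by more than their counting error (3 before that error). This share lies between the bounds set for either reading, but rests on Olfr112 alone. Reads not placed uniquely stay out of the gene counts, so values of related receptors may be too low and are uncertain. Without Olfr112 the bound for Sirpa+ DCs as the only source would be met, but the test cannot decide this. It counted low shares only, in genes whose PBS pDC level was under 5% of the Sirpa+ DC level. Shares above the median were not counted, and the MHC class II genes below were left out. Over the 203 other genes the quartiles of the share were 6.29% and 32.0% in YG+ pDC replicate 1. In replicate 2 they were 4.47% and 20.5%. The MHC class II genes H2-Ab1 (9239 ± 1499 CPM in Sirpa+ DCs, 2534 ± 141 in PBS pDCs and 2139 ± 358 in YG+ pDCs) and H2-Aa (5734 ± 1252, 1683 ± 407 and 1660.4 ± 83.3), however, were not higher in YG+ pDCs. H2-Eb1 (6416 ± 1306, 1183 ± 176 and 1603 ± 194) and Ctss (1119 ± 410.3, 257 ± 29.5 and 531 ± 88.6) had higher means there. A response of pDCs to the tumour or the microspheres, or another state of the cells that take them up, remains open and untested.

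Macrophages among the YG+ pDCs were tested with 11 genes of resident macrophages, whose summed levels were 336 and 123 CPM in YG+ pDCs, 395 and 104 CPM in PBS pDCs, and 288 and 281 CPM in Sirpa+ DCs. Of these genes 10 and 8 were detected (any count) in the YG+ libraries, 4 and 6 in the PBS pDC libraries and 6 and 8 in the Sirpa+ DC libraries. The YG+ libraries also had the highest gene totals (713966 and 565406, against 177844 to 525418 in the others), and depth alone can raise detection. The gate on B220 should remove macrophages. The most abundant, Cd163, was 72.1 ± 31.1 CPM in YG+ pDCs and 179 ± 152 CPM in PBS pDCs. The lowest YG+ library had 0.312 of the highest PBS library, and by the bound first written for this test, neither YG+ library above the highest PBS pDC library, macrophages would have been excluded. That reading was set aside after the outcome was seen, because Cd163 made 72.6% of the 62 counts behind the deciding sum in PBS pDC replicate 1, so the test is treated as deciding nothing. Without Cd163 the sums were 242 and 73.4 CPM in YG+ pDCs, 108 and 32.4 CPM in PBS pDCs, and 118 and 146 CPM in Sirpa+ DCs, which meet neither the bound for macrophages nor that against them.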
